A study of Mus musculus with 8 samples.

How the data were processed

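Cells were taken from micro-dissected mammary ducts and terminal end buds of mice of 5 weeks, dissociated, sorted live into plates and processed by SORT-seq, an automated form of CEL-seq2 that tags each well and each transcript molecule, per the labels' protocols. Libraries were read as 75 bp pairs on a NextSeq500, per the labels' protocols. BWA 0.6.2-r126 and the genome build mm10 are named in the submitters' processing notes, which give no role or settings for them. The deposited table holds expected counts, that is estimated numbers of transcript molecules per gene and well. Its values follow the correction for 2 molecules sharing a tag that a pool of 4-base tags would need, as read from the values. Of 533078 values above 0, 533073 fell on that scale within a tolerance of 1e-06 after the correction was undone. The authors' other filters are not given in the sources used here. The table has 14883 gene lines and 81 spike-in lines, and no mitochondrial gene, so the planned mitochondrial filter removed nothing.

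Counts were rounded to whole numbers and spike-ins kept out of totals. Wells were kept as cells with at least 1500 transcripts and at least 500 genes, which left 114 of 121 wells that reached 1500 transcripts. Kept cells ranged in median from 4872 to 21255 transcripts per library. Spike-in totals had a median of 264 in wells under 500 transcripts and 321 in kept wells. Each cell's transcripts were split at random, 50% to each part. Clusters were made on the first part with scanpy 1.11.5 (1000 variable genes, 15 components, 15 neighbours, Leiden resolution 1.0) and named there from markers fixed before the data were examined. Tests between classes used the other part, so that clustering did not choose the tested counts. The plate comparison used all transcripts. A marker counted for a cluster when found in 25% of its cells and at 2 times the lower quartile of the other clusters, and 3 markers were needed. This naming rule was set after the data were seen and before any test. An earlier form with the median in place of the quartile left clusters unnamed in some alternatives and gave the same main classes. The form used also left 10 cells unnamed with another seed for the split. Clusters 0, 1 and 5 were basal-like, cluster 2 secretory-like, cluster 3 hormone-sensing-like and cluster 4 endothelial-like. Scrublet called 2 of 114 cells as doublets, and 1 of 41 luminal-like cells held 10 or more basal marker transcripts. Of all 114 cells, 20 held at least 10 transcripts of both the basal and the luminal list. None was removed.

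Transcripts of the held-out part were summed per library and class and tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. DESeq2 1.42.0 was an alternative. The standard error is the log2 change over the root of the F statistic and is approximate. CPM are counts of the tested genes scaled to the library's total after TMM. The planned basal-like against luminal-like fit used the library as block with at least 5 cells of both classes, which no library met. The fit reported is the fit without the block, listed beforehand, 4 basal-like against 4 luminal-like sums. For the luminal classes no library had 5 cells of both, so at least 3 cells were required, a number set after cells were counted and before the test. That left 3 libraries with 3 to 9 cells per sum. Depth was uneven, with a median of 15538 transcripts in hormone-sensing-like and 7460 in secretory-like cells. In plate 2 library 1 the 2 sums held 73091 and 6178 transcripts in that order. P-values of that fit, down to 4.49e-40 for Igfbp5 among named genes, rest on the spread pooled over genes. Plates were compared on sums of all transcripts of all epithelial-like cells, not of the held-out part alone. Shares were compared by exact permutation.

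Named genes followed a rule set before the data were examined. It took the 10 largest changes each way among genes past the threshold with the same sign on both plates, leaving out naming markers, ribosomal protein genes and pseudogenes. It also took up to 4 passing and 2 other members of each fixed list. The sign per plate came from summed ratios on each plate, not from separate fits. The 21 gene lists, also set before the data were examined, were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and beside it an estimated one. The estimated form uses the residual degrees of freedom of the fit. These are few for the luminal classes and for the clusters, so lists can hardly pass it there. Lists with under 3 tested genes had no set test. Markers of fibroblasts, endothelium, pericytes, macrophages, lymphocytes, adipocytes, nerve and red blood cells had at most 1 gene tested per list and 0 past the threshold in each comparison. With so few tested, these lists cannot show whether RNA of such cells entered the sums.

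Library numbers were checked as pairs across plates by the correlation of deviations from the plate means over 3571 genes. It was 0.36, 0.41, 0.57 and 0.63 for numbers 1 to 4, while plate 1 library 1 correlated better with plate 2 library 3 (0.53) and plate 1 library 4 with plate 2 library 2 (0.65). The labels do not say that a number marks anything shared. No 2 libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 2.54. On simulated data with known changes, the basal-like against luminal-like step over 1645 genes recovered 41.4%, 91.8% and 100% of genes changed 2, 4 and 8-fold. The luminal step over 1107 genes recovered 7.46%, 52.2% and 84.8%, and the plate step over 3571 genes 4.17%, 38.8% and 78.7%. False calls were 5.52%, 1.03% and 7.23% of all calls for the basal-like against luminal-like, luminal and plate steps. Simulated counts varied independently around 1 mean per gene, without library or cell class effects, so recovery in the real data may differ. Cells drawn from 1 simulated class gave 0 calls with and without splitting, so that test did not show that splitting was needed. Gene positions come from the GENCODE annotation of mm10. Alternatives changed the scaling, filters, cell minimum, resolution, seed, counts used, block and libraries.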

Results

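Single cells from the pubertal mouse mammary gland, taken at 5 weeks of age, were profiled to find basal and luminal cell types. The labels name 8 libraries, 4 on plate 1 and 4 on plate 2, of 96 wells each. They do not say which library came from ducts and which from terminal end buds, the growing tips of the ducts, nor which libraries came from separate animals. The p-values below therefore measure the spread between libraries, which may be technical. On plate 1 the libraries numbered 1 to 4 held 126854, 101158, 220249 and 125004 transcripts. On plate 2 they held 182290, 598625, 212449 and 374415 transcripts. Of 768 wells, 114 were kept as cells, 14.8% (exact binomial 95% interval 12.4 to 17.6), and 579 wells held under 500 transcripts. Intervals on shares and ratios cover counting error only.

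Kept cells fell into 67 basal-like, 41 luminal-like and 6 endothelial-like cells. The luminal-like cells were 15 hormone-sensing-like and 26 secretory-like cells, the latter 2 names standing for the estrogen-responsive and the milk-lineage luminal cells. The marker genes used to name the classes are given as a check of the names. Acta2, smooth muscle actin, made up 77.1 of 10000 transcripts in basal-like cells, 0.886 in hormone-sensing-like and 0.0688 in secretory-like cells. Krt8, a luminal keratin, made up 1.97, 30.2 and 9.63 of 10000 transcripts in the same order. Prlr, the prolactin receptor, stood at 30.5 of 10000 in hormone-sensing-like and 1.79 in secretory-like cells, and Trf, transferrin, at 0.886 and 108.

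Basal-like cells were 62.0% of the 108 epithelial-like cells (exact binomial 95% interval 52.2 to 71.2). The share differed widely between libraries, with a mean of 55.8% ± 47.9 (SD, n = 8). All epithelial-like cells of libraries 2 and 4 were basal-like on both plates, 7, 6, 31 and 18 cells. Of those 7 and 6 cells, 4 and 1 held more transcripts of another cell type's marker list than of all epithelial lists. Libraries 1 and 3 held 3 of 10 and 1 of 13 basal-like cells on plate 1, and 1 of 11 and 0 of 12 on plate 2. The 4 basal-like cells of plate 1 libraries 1 and 3 all held more transcripts of another cell type's marker list than of all epithelial lists. With such cells set aside, a choice made after seeing the data, the share was 0% in plate 1 libraries 1 and 3. It stayed 100% in libraries 2 and 4, on 3 and 5 cells on plate 1, and the mean was 51.1% ± 52.3 (SD, n = 8). The share was 59.4% ± 47.7 on plate 1 and 52.3% ± 55.2 on plate 2 (SD, n = 4 each), and an exact permutation test over 70 splits did not separate the plates (two-sided p = 0.83, smallest possible 0.0286). Paired by library number, a test added after seeing the data, the share was lower on plate 2 in 2 of 4 pairs and equal in the others, with a mean difference of -7.15 points (exact p = 0.5, smallest possible 0.125 for 4 pairs). With the other-type cells set aside, no pair was lower and library 1 was higher, at 9.09% on plate 2. A sort gate or the tissue part could set these shares, and the labels give neither per library.

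**Figure D1:**
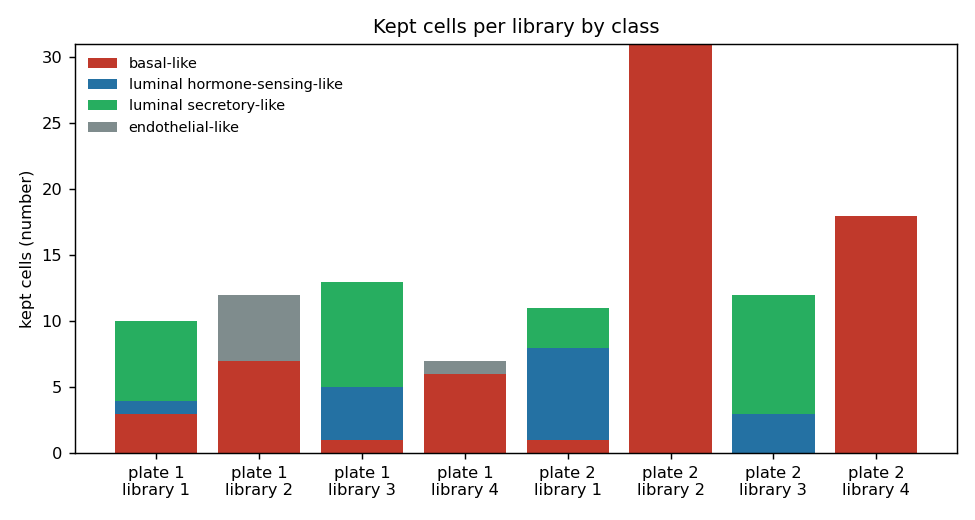
Number of kept cells (y axis) in each of the 8 libraries (x axis), with colours for the 4 classes. Libraries 2 and 4 of both plates hold no luminal-like cell, and the largest library has 31 cells.

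Basal-like cells were higher than luminal-like cells in matrix and contractile genes, and lower in junction genes. Cxcl14, a chemokine, stood at 1311 ± 474 CPM in the 4 basal-like libraries and had 0 transcripts in the 4 luminal-like ones, at least 105-fold higher (SD, n = 4 each). Myh11, the smooth muscle myosin heavy chain, was at least 97.7-fold higher and Vcan, a matrix proteoglycan, at least 59.8-fold higher. On the luminal side, Aqp5, a water channel, stood at 370 ± 170 CPM with 0 transcripts in basal-like libraries, at least 44.3-fold lower in basal-like cells, and Basp1 was at least 109-fold lower. Bounds for genes with 0 transcripts set the group at a floor of 3 transcripts over all its libraries and pool the other group's transcripts, so deeper libraries weigh more. With libraries weighted alike on the same floor, the bounds for Cxcl14, Myh11, Vcan, Aqp5 and Basp1 were 89.3, 84.3, 49.8, 45.3 and 114-fold, and those of all named genes 0.731 to 1.26 times the pooled ones.

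All 8 tested members of the basement membrane and matrix list rose in basal-like cells (8 adjusted over the list alone). Col4a1, a basement membrane collagen chain, had 1389 transcripts in basal-like and 1 in luminal-like sums, a ratio of 774 (counting interval 139 to 30596). Sparc, a collagen-binding matrix protein, had 1562 and 2, a ratio of 435 (120 to 3597), and Col4a2 had 799 and 2, a ratio of 223 (61.4 to 1842). Lamb1, a laminin chain, rose by 5.03 ± 0.54 on the log2 scale (SE, n = 4 each). The list was higher by camera (adjusted p = 1.23e-14, and adjusted p = 0.025 with an estimated correlation).

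Contractile and actin-binding genes rose in 9 of 11 tested cases (10 adjusted over the list alone). Contractile markers, among them Acta2 and Tagln, also named the basal-like clusters, so the direction of this list was not independent of the naming. The tropomyosins Tpm2 and Tpm1 had log2 changes of 4.79 ± 0.56 and 2.67 ± 0.36, and Cald1, caldesmon, of 3.66 ± 0.43 (SE, n = 4 each). Calm2 and Cav1 had log2 changes of 0.34 ± 0.23 and 1.67 ± 0.71 and did not pass. Camera gave adjusted p = 3.67e-10, and adjusted p = 0.0469 with an estimated correlation. The integrins Itga6 (2.41 ± 0.45) and Itgb1 (1.19 ± 0.26) were the members past the threshold among 6 tested hemidesmosome and integrin genes (2 adjusted over the list alone). That list passed with the preset correlation (adjusted p = 0.0429) and not with an estimated one (adjusted p = 0.242 with an estimated correlation).

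Tight junction and apical polarity genes fell in 3 of 5 tested cases (4 adjusted over the list alone), by camera with adjusted p = 8.16e-06, and adjusted p = 0.0469 with an estimated correlation. The junction genes Cldn3, Cldn4 and Cldn7 were naming markers of luminal-like cells, so this direction was not independent of the naming either. Cdh1, the epithelial cadherin, had a log2 change of -2.98 ± 0.32, Epcam of -2.87 ± 0.29 and Ezr, ezrin, of -2.21 ± 0.30 (SE, n = 4 each). F11r and Cd9 had log2 changes of -0.96 ± 0.34 and -0.26 ± 0.27 and did not pass. Among other genes higher in luminal-like cells were Clu, the chaperone clusterin (-5.21 ± 0.67), Dhrs3, a retinal reductase (-4.79 ± 0.59), Me1, malic enzyme (-4.66 ± 0.68), and Inhbb, an activin subunit (-4.64 ± 0.63). Tgm2, Agps and Alcam had log2 changes of -4.32 ± 0.69, -4.04 ± 0.77 and -3.96 ± 0.51. Mlph had 57 luminal-like and 2 basal-like transcripts, 51.1-fold lower in basal-like cells (counting interval 13.5 to 432). Id4, Igfbp2, Col18a1, Sdpr, Il17b and Bmp7 had 0 luminal-like transcripts and were at least 44.6, 49.0, 41.2, 40.7, 42.5 and 17.8-fold higher in basal-like cells.

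The other lists did not pass as sets, with adjusted p of 0.0979 or more. In the interferon response and MHC list 4 of 8 members fell (4 down and 2 up adjusted over the list alone), among them the MHC class I genes H2-D1 (-2.47 ± 0.37), H2-K1 (-2.09 ± 0.36) and B2m (-1.23 ± 0.32). Ifitm3 and Irf1 had log2 changes of 1.37 ± 0.44 and 1.48 ± 0.56. The hormone response list had 2 of 5 members down, Gata3 (-2.35 ± 0.40) and Xbp1 (-1.31 ± 0.36). The growth factor list (FGF, TGF-beta and BMP) had 3 of 9 up and 2 down, with Tgfbr3 up by 4.98 ± 0.72 and a median log2 change of -0.27 against a mean of 1.12. The stem or progenitor-associated list had 1 of 5 up, Cxcl14, and 3 down, Cd24a (-2.41 ± 0.47), Sox9 (-1.70 ± 0.37) and Runx1 (-1.68 ± 0.36), with a median of -1.68 and a mean of 0.89. The Wnt list had 1 of 4 up, Tcf7l1, at a ratio of 19.3 (counting interval 6.43 to 95.2), with a median of -0.29 and a mean of 0.61. Immediate early genes had 2 of 19 up, Egr1 (1.00 ± 0.21) and Egr2 (2.75 ± 0.69), and Dusp1 down (-1.77 ± 0.33; 2 up and 2 down adjusted over the list alone). The histone list had 1 of 3 up, the nucleosome-binding protein Hmgn2 (1.03 ± 0.29), while the histones H2afz (0.82 ± 0.41) and H1f0 (-0.57 ± 0.50) did not pass. Oxidative phosphorylation had 1 of 20 down, Cox6b1 (-0.95 ± 0.27), and the antioxidant and metal list 1 of 10 down, Gpx1 (-1.07 ± 0.32). The last 2 lists had 0 adjusted over the list alone. Glycolysis and hypoxia had 0 of 9. Of the lists too small for a set test, cytokines had 2 of 2 down, the naming marker Lcn2 (-2.28 ± 0.65) and Nfkbia (-1.40 ± 0.40), while milk (1 tested), Notch (2), EGF receptor family (1), S phase (1), G2/M (2) and lipid synthesis (1) had 0. Mfge8 of the milk list was 1 down adjusted over the list alone.

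In all, 270 of 1645 tested genes passed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 159 higher and 111 lower in basal-like cells. Each library entered the fit with 1 class, so class and library cannot be told apart. The count was 409 without plate 1 library 1 and 453 without plate 1 library 2, 408 with plate as covariate, 626 on plate 2 alone and 58 on plate 1 alone. Of the 67 basal-like cells, 9, all on plate 1, held more transcripts of another cell type's marker list than of all epithelial lists, and with such cells set aside the count was 453. That setting also took plate 1 library 2 under the 5-cell minimum (4 of its 7 basal-like cells), so the 2 changes cannot be separated. In that library the leading other list was fibroblast for 2 cells, nerve or Schwann for 1 and red blood cell for 1. Plate 1 library 4 had 1 endothelial-led cell. These cells were part of the basal-like sums tested. Plate 1 library 1 had 2 cells led by macrophage or dendritic markers and 1 by lymphocyte markers, and library 3 had 1 led by red blood cell markers. Cxcl14 lies on chromosome 13 at 56288643 to 56296551, Myh11 on chromosome 16 at 14194535 to 14291372, Col4a1 on chromosome 8 at 11198423 to 11312826, Aqp5 on chromosome 15 at 99590782 to 99594829 and Basp1 on chromosome 15 at 25363277 to 25413764, all protein-coding genes of mm10.

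**Figure D2:**
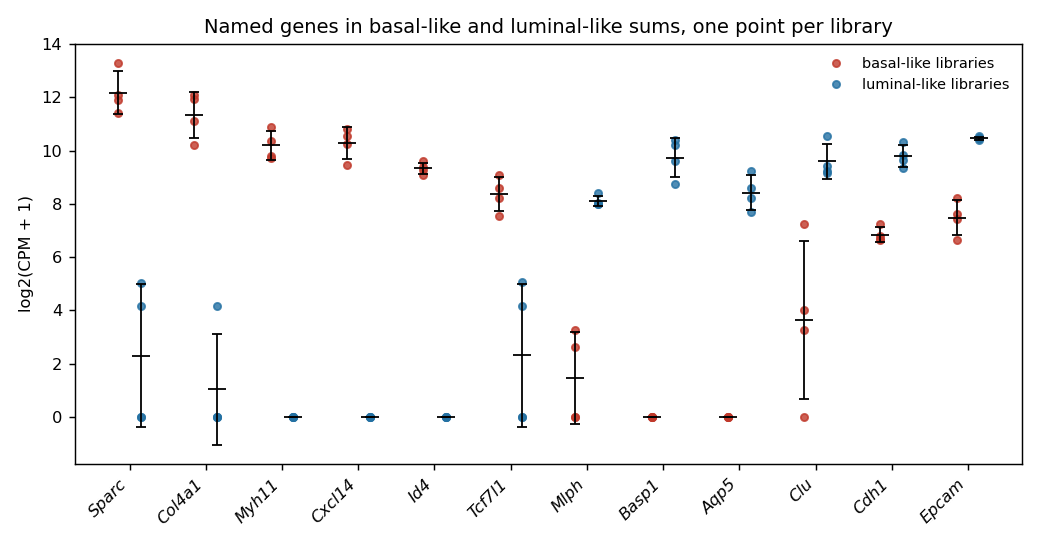
Log2(CPM + 1) on the y axis for 12 named genes on the x axis, 1 point per library, red for the 4 basal-like and blue for the 4 luminal-like libraries, with the mean and SD in black. Points at 0 are libraries with 0 transcripts, as for Cxcl14 and Myh11 in luminal-like and Basp1 and Aqp5 in basal-like libraries.

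Within the luminal-like cells, Igfbp5, an IGF-binding protein, and Cst3, the protease inhibitor cystatin C, were lower in hormone-sensing-like than in secretory-like cells, with log2 changes of -6.14 ± 0.44 and -6.18 ± 0.45 (SE, n = 3 library pairs). Spp1, osteopontin, had -5.96 ± 0.55. Hormone-sensing-like cells were higher in Fgfr2, a fibroblast growth factor receptor, with 157 against 2 transcripts, a ratio of 43.8 (counting interval 11.9 to 365), and in Id3, at least 18.1-fold. Ratios and fold bounds for the luminal classes pool transcripts over libraries and leave out the pairing, so they can differ from the paired fit. The paired log2 change of Fgfr2 was 5.15 ± 0.83.

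All 5 tested milk and secretory product genes fell in hormone-sensing-like cells (5 adjusted over the list alone). Mfge8, a milk fat globule protein that is also a naming marker, had a log2 change of -5.45 ± 0.51, Btn1a1, butyrophilin, of -5.36 ± 0.65 and Cp, ceruloplasmin, of -4.58 ± 0.70 (SE, n = 3 pairs). Camera gave adjusted p = 1.67e-08, and adjusted p = 0.73 with an estimated correlation. With 3 pairs the estimated form had few degrees of freedom, so it cannot decide on this list. Milk genes such as Csn3 and Lalba named the secretory-like cluster, so the direction of this list was not independent of the naming. Atp6v1b1, a proton pump subunit, and Foxi1, a forkhead transcription factor, had 0 transcripts in hormone-sensing-like cells and were at least 22.1 and 13.1-fold lower there. Sepp1, Kcnk5, Fads1, BC006965 and Fut9 were at least 23.9, 14.9, 12.5, 16.7 and 15.5-fold lower.

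Interferon response and MHC genes rose in 4 of 6 cases (4 adjusted over the list alone). B2m, the MHC class I light chain, had a log2 change of 2.02 ± 0.44, H2-D1 of 1.80 ± 0.36, H2-K1 of 1.36 ± 0.41 and Psmb8, an immunoproteasome subunit, of 3.21 ± 0.83. Ifitm2 and Ifitm3 had -0.08 ± 0.60 and 0.95 ± 0.69. The set passed camera with adjusted p = 0.0291, and had adjusted p = 0.73 with an estimated correlation, again on few degrees of freedom. Gpx3, a peroxidase, had a ratio of 60.01 (counting interval 16.4 to 498.7), Ido1 of 25.9 (8.67 to 127), Adra2a, an adrenergic receptor, of 31.3 (5.39 to 1257) and Tspan1 of 37.4 (6.49 to 1499). Their paired log2 changes were 5.55 ± 0.84, 5.12 ± 0.91, 5.22 ± 1.12 and 5.28 ± 1.07 in that order. Il8 as listed, Itih2, Tmem158 and AW112010 were at least 12.7, 11.2, 11.2 and 9.30-fold higher.

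No other list passed as a set, with adjusted p of 0.329 or more. Hormone response genes had 2 up and 1 down of 4, with Gata3 up (1.25 ± 0.44) and Igf1r down. Igf1r had 39 against 1 transcripts, 69.9-fold lower when pooled (counting interval 11.8 to 2829), and a paired log2 change of -5.18 ± 1.11. In the Wnt list Wnt5a rose (3.89 ± 0.80) and Tcf7l2 fell (-2.97 ± 0.72), 1 each of 3, with a median of -0.46 and a mean of 0.15. Both tested Notch members fell, Hes1 (-1.98 ± 0.58) and Notch1 (-2.05 ± 0.76). The growth factor list had 2 up, Id3 and Fst, and 3 down, among them Id2 and Tgfb3 (-3.66 ± 0.90), of 7 (2 up and 4 down adjusted over the list alone). The antioxidant and metal list had 3 up, Gpx3 and the metallothioneins Mt1 (2.36 ± 0.62) and Mt2 (4.23 ± 0.65), and Txnip down, of 11 (3 up and 2 down adjusted over the list alone). Immediate early genes had 3 of 18 down, Egr1 (-2.10 ± 0.41), Fos (-1.49 ± 0.33) and Nr4a1 (-1.42 ± 0.54; 2 down adjusted over the list alone). Glycolysis had 2 of 7 up, Aldoa (1.96 ± 0.67) and Pkm (1.56 ± 0.55), and the histone list 1 of 3 up, H1f0 (3.08 ± 0.87). With at least 5 cells and no replicate block, Mt1, Aldoa and H1f0 had the other sign (-1.49, -0.079 and -1.58). The stem or progenitor-associated list had Cd24a up (1.47 ± 0.38) and Sox10 down (-3.92 ± 0.84) of 4. Cytokines had Il33 up and Lcn2 down (-5.00 ± 0.48) of 4. Il33 had a pooled ratio of 42.4 (counting interval 7.39 to 1698) and a paired log2 change of 5.00 ± 1.06. Hemidesmosome genes had Cd44 down (-3.02 ± 0.82) of 3 (1 up and 2 down adjusted over the list alone). The cytokine list had a median of 0.35 and a mean of 0.17 with camera's direction down. Contractile (4 tested), tight junction (6), oxidative phosphorylation (14), EGF receptor family (1), S phase (1), G2/M (1) and lipid synthesis (1) had 0, and no basement membrane gene was tested.

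In all, 209 of 1107 tested genes passed in edgeR with library as block, 101 higher and 108 lower in hormone-sensing-like cells. The secretory-like sum of plate 2 library 1 was shallow, with 6178 transcripts against 73091 in its hormone-sensing-like sum. The count was 76, 82 and 100 without plate 1 library 3, plate 2 library 1 and plate 2 library 3, and 123 by DESeq2. Without the replicate block it was 139, and within plate 1 there was 1 pair, too few for a fit. Fgfr2 lies on chromosome 7 at 130162451 to 133123350, Id3 on chromosome 4 at 136143497 to 136145755, Cst3 on chromosome 2 at 148871722 to 148875692 and Igfbp5 on chromosome 1 at 72857932 to 72874884, all protein-coding.

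**Figure D3:**
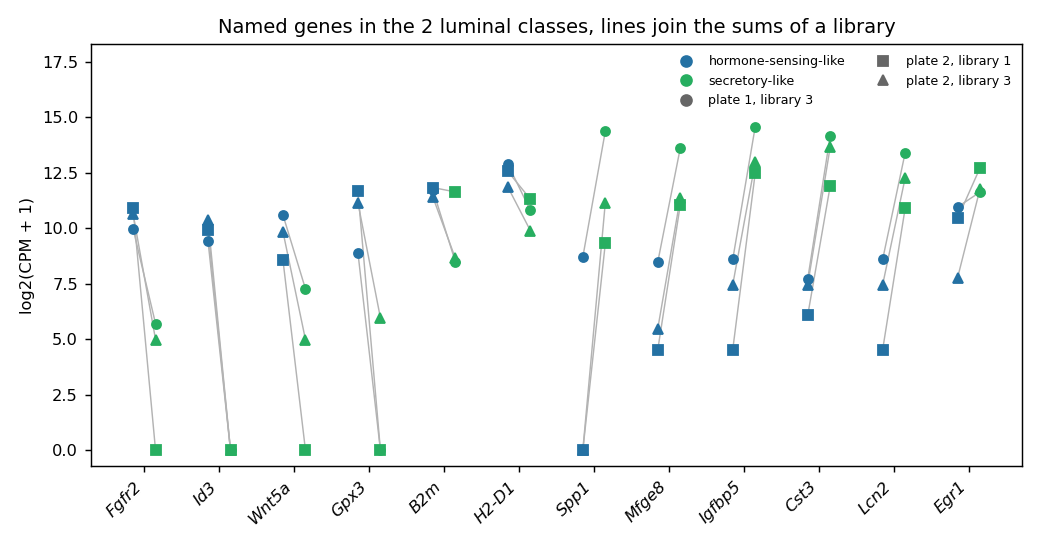
Log2(CPM + 1) on the y axis for 12 named genes on the x axis, blue for hormone-sensing-like and green for secretory-like sums, with 1 marker shape for each of the 3 libraries and lines joining the sums of a library. Points at 0 are sums with 0 transcripts, as for Id3 in all 3 secretory-like sums.

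Between plates, no gene passed among 3571 tested over all epithelial-like cells. Each plate mixed basal-like and luminal-like libraries, which widens the spread within a plate. On simulated data this step recovered 4.17% of genes changed 2-fold, so smaller differences between plates can be missed. Sparc stood at 2488 ± 3467 CPM on plate 1 and 1736 ± 2009 on plate 2, and Gapdh, a glycolytic enzyme, at 1965 ± 318 and 1530 ± 103 (SD, n = 4 each). Mfge8 had a log2 change from plate 1 to plate 2 of -1.52 ± 0.92 and Spp1 of -2.65 ± 2.15 (SE). Plate 2 cells were deeper, with a median of 14405 ± 5732 transcripts per kept cell against 6004 ± 1147 (SD, n = 4 each, exact permutation p = 0.0286, two-sided, the smallest possible). Cells with more transcripts of another type's markers than of epithelial ones numbered 16 on plate 1, 6 of them endothelial-like, and 0 on plate 2 (exact permutation p = 0.0286, n = 4 each). Paired by library number, each of these 2 had exact p = 0.125, the smallest that 4 pairs can give, with the same direction in 4 of 4 pairs. Median spike-in per well was lower on plate 2 in 4 of 4 pairs too, 260 ± 19.5 against 329 ± 68.4 (SD, n = 4 each, exact permutation p = 0.0857, paired exact p = 0.125).

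Both edgeR and DESeq2 passed 0 genes, with 103 and 104 at an unadjusted p under 0.05, and edgeR with the library number as replicate block passed 0 with 194. With class as covariate, a fit added after seeing the data, edgeR passed 0 of 4247 genes, with 217 at an unadjusted p under 0.05. The 3 fixed lists that passed were lower on plate 2 by camera with a preset correlation, namely glycolysis and hypoxia (11 tested, adjusted p = 0.00139), antioxidant and metal genes (11 tested, adjusted p = 0.0211) and milk and secretory products (5 tested, adjusted p = 0.0368). None of their members passed alone or adjusted over the list alone, and each had adjusted p = 0.931 with an estimated correlation. The milk list had adjusted p = 0.0959 without its naming marker Mfge8. Luminal secretory naming markers (8 tested) had a median log2 change of -1.22 and hormone-sensing ones (3 tested) of 0.94, with 0 past the threshold. Whether the make-up of cell classes entered the milk call was not tested. The other lists had 0 members past the threshold and adjusted p of 0.0959 or more, and the EGF receptor family list (2 tested) was too small. Camera's direction differed in sign from the median or mean for hormone response (median -0.10, mean 0.01), growth factors (0.03 and 0.08, direction down), G2/M (-0.05 and 0.18) and cytokines (0.25 and -0.08). A test of whether the difference between basal-like and luminal-like cells itself differed between plates passed 0 of 2657 genes in edgeR, with 111 at an unadjusted p under 0.05.

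Ducts and terminal end buds were not compared, since the labels and columns used here do not tie a library or well to either.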

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

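The haemoglobin tests in this part were chosen after the result was seen. A library that stood apart from the other 3 of its group was found in 22 of 262 groups examined, where chance would give about 13.1. The chance figure holds only for independent groups of normally spread values, and low counts need not follow it.

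Plate 1 library 2 held 9 cells with more transcripts of another cell type, against 2 or 3 in the other plate 1 libraries. In the basal-like sums the same library stood apart for Clu (149 CPM), Fth1 (2288), H2-K1 (895), Scd2 (1741), Tgfbr3 (1442) and Fgfr2 (0 CPM, the lowest). Among the plate 1 sums of all epithelial-like cells it stood apart for Pcna (755 CPM) and Scd2 (1278). Plate 1 library 4 stood apart among basal-like sums for H2-D1 (990 CPM) and Inhbb (150.0), and plate 2 library 4 for Sdpr (748). Among luminal-like sums plate 1 library 1 stood apart for Clu (1497 CPM) and Ftl1 (2581) and plate 2 library 1 for Cav1 (544) and Mlph (338). Plate 1 library 3 stood apart for Col4a1 (17.1 CPM), which is only 1 transcript. In the plate comparison plate 1 library 1 stood apart for Cox8a (1084 CPM) and Ftl1 (2049), plate 2 library 1 for Cd9 (1182) and Fgfr1 (136), and plate 2 library 3 for Spp1 (988).

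Outside the comparisons, 6 endothelial-like cells appeared, 5 in plate 1 library 2 and 1 in plate 1 library 4, 5.26% of kept cells (exact binomial 95% interval 1.956 to 11.1). They held all 8 fixed endothelial markers, Pecam1, Cdh5, Kdr and Emcn among them.

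The 7 wells with at least 1500 transcripts and under 500 genes were led by haemoglobin, with a median of 79.1% of transcripts (range 68.9 to 93.3), against 0.0146% in kept cells. Haemoglobin in the epithelial-like cells differed between libraries and rose with the haemoglobin transcripts in haemoglobin-rich wells of the same library (r = 0.987, rho = 0.994, n = 8, exact permutation p = 9.92e-05 each, adjusted p = 0.000198 over 2 relations). Epithelial-like cells with more transcripts of another cell type were left out of these values. Without the 2 farthest libraries r was 0.918. Within plates r was 0.982 over both, and rho was 1 on plate 1 and 0.949 on plate 2 (576 arrangements within plates, exact permutation p = 0.00347 for r and 0.00694 for rho over both, the smallest possible for each). RNA from red blood cells of the same library is thus a candidate explanation, while expression by the epithelial-like cells themselves stays open. The 2 libraries without haemoglobin-rich wells, the basal-like libraries 2 and 4 of plate 2, had at most 0.000341% haemoglobin in these cells. The basal-like libraries 2 and 4 of plate 1, with 1 such well each, had 0.0377% (3 cells) and 0.0122% (5 cells). Among basal-like libraries haemoglobin thus went with such wells, but the plates differed too. No luminal-like library lacked such wells, and no biological explanation was tested.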

How the results depend on the processing

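Settings on set-aside cells, plates, the median naming rule, plate as covariate and at least 5 cells without a block were chosen after seeing the data. The basal-like against luminal-like count of 270 genes was 1146 with no filter on low counts (13555 tested), 530 with all transcripts, 476 with another seed, 455 at resolution 2.0, 537 with counts summed per plate, 546 with at least 10 cells and 36 with cells thinned to 1500 transcripts (240 tested). With other-type cells set aside it was 453, as without plate 1 library 2, whose sum that setting lost. It was 408 with plate as covariate, 626 on plate 2 alone and 58 on plate 1 alone. Leaving out each library gave 208 to 453. The luminal count of 209 was 100 with no filter, 123 by DESeq2, 139 without the replicate block and 21 when thinned (136 tested). Leaving out each library gave 76 to 209, the last for libraries outside the fit. Of these settings, all but DESeq2 and leaving out libraries outside the fit also changed the number of sums or of tested genes, and the cause was not tested. Basal-like sums fell from 4 to 3 at resolution 2.0, when thinned and with other-type cells set aside, and to 2 with another seed, at least 10 cells, counts per plate and each plate alone.

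With an estimated correlation the luminal lists went from 2 to 0, on few degrees of freedom, and the plate lists from 3 to 0. The plate count was 0 genes at each setting run, with the replicate block too, and lists were not run with it between plates. The basal-like share of 55.8% ranged from 49.5% to 63.8% when each library was left out. With the median naming rule and another seed it was 42.9% over 7 libraries, with 27 cells unnamed and no value for plate 1 library 2.

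Among named genes, 33 of 2138 basal-like against luminal-like values had the other sign, all for 10 genes past the threshold in neither fit, and 107 lost and 38 gained the threshold. For the luminal classes 137 lost it, 11 gained it, and 59 of 1484 values had the other sign for genes past it in neither fit, as did 84 of 918 for plates. H1f0 (-1.58), Aldoa (-0.079) and Mt1 (-1.49) changed sign with at least 5 cells and no replicate block, where hormone-sensing-like cells are 1 library assumed to vary like the others, and the cause was not tested. No paired analysis of basal-like against luminal-like genes was possible at the planned minimum of 5 cells of both classes per library. Plate 1 libraries 1 and 3 and plate 2 library 1 held 3, 1 and 1 basal-like beside 7, 12 and 10 luminal-like cells. A lower minimum was not run for these classes. For the luminal classes at least 10 cells gave no value. The Kcnq1ot1 filter removed 0 cells. Depth limits each comparison to the more abundant genes.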

Other observations

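The cluster comparison, the splits and the tests on library make-up were chosen after the result was seen, and the 2 well number tests before their own values, though their intervals were added later.

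Basal-like cells fell into clusters 0, 1 and 5. In the held-out transcripts of plate 2 libraries 2 and 4, cluster 0 had higher G2/M genes than cluster 1 in 3 of 4 tested cases, such as Mki67, a proliferation gene (log2 change 3.72 ± 0.88), and Hmgb2 (2.09 ± 0.43, SE, n = 2 library pairs). The histone list rose in 2 of 3 cases, the histone H2afz (2.05 ± 0.36) and the nucleosome-binding protein Hmgn2 (1.99 ± 0.37). Pcna had 0.44 ± 0.39 and Cenpf -0.80 ± 0.57 and did not pass. Contractile genes fell in 10 of 14 cases, Myh11 among them (-4.73 ± 0.43), as did 10 of 14 basement membrane and matrix genes and 8 of 18 immediate early and dissociation genes. Oxidative phosphorylation had 5 of 18 up, glycolysis 2 of 7 up, and the antioxidant list 4 of 8 up and 1 down. The set calls of these 8 lists were not reached with an estimated correlation (adjusted p = 0.643 for G2/M genes, 0.609 for the others). With 2 pairs that form had very few degrees of freedom in the cluster comparisons, so it cannot decide on these lists. In all 171 genes were higher and 234 lower of 1804, with 2 pairs and no further replicate. Cluster 0 cells were also deeper, with a median of 21923 transcripts against 7533 in cluster 1 and 16385 in cluster 5 over all libraries, and depth was not matched in this comparison. Cluster 5 against cluster 1 had 10 genes higher and 35 lower of 1628, with 1 of 14 contractile and 4 of 18 immediate early genes lower. Both lists had camera adjusted p = 2.9e-07, and adjusted p = 0.792 with an estimated correlation, so the preset call for these lists was not particular to cluster 0.

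Cluster 0 cells lay in lower well numbers, wells 2 to 33 in plate 2 library 2 (10 cells) and 2 to 24 in library 4 (3 cells), a mean difference of 29.1 wells from other basal-like cells (permutation p = 0.00035). That permutation was not among the planned tests. It takes cells and not libraries as units, so its p-value does not measure the spread between libraries. In library 2 the median wells of clusters 0, 1 and 5 were 9, 48 and 41.5, but in library 4 they were 22, 38.5 and 12, so there the low position was shared with the 3 cells of cluster 5. On plate 1, other-type cells left out, luminal-like cells lay in wells 42 to 96 (library 1) and 61 to 96 (library 3). Basal-like cells there lay in wells 64 to 91 (library 2) and 51 to 86 (library 4). No low well position was thus seen among those plate 1 cells. A spike-in recovery that falls with well number is argued against by Spearman coefficients of 0.0572 and 0.0332 over 96 wells each, with lower limits of -0.145 and -0.168 where a fall beyond -0.3 was required. A transcript yield that falls with well number stays open, with coefficients of 0.116 (21 cells, interval -0.333 to 0.521) and -0.179 (15 cells). The order of sorting or the tissue part may also differ along wells, which the labels do not give, and no biological explanation was tested.

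Libraries 1 and 3 held mostly luminal-like cells and libraries 2 and 4 basal-like cells on both plates. Whether most wells dropped by the transcript filter in libraries 2 and 4 held luminal-like cells stays open. Their wells of at least 50 and under 500 transcripts held 4 Krt8 transcripts (upper Poisson limit 10.2), where secretory-like cells alone would give 40.1. The RNA in those wells thus held little Krt8. Whether it came from the sorted cell was not tested, and wells under 50 transcripts were not counted, so the count cannot decide. That the filter dropped basal-like cells of libraries 1 and 3 stays open, since Acta2 reached 14.9 of 10000 there but was higher in such wells than in kept cells in 8 of 8 libraries. A sort gate or tissue part that differed between libraries cannot be told apart from cell type, as 0 libraries have labels that name one.

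For basal-like against luminal-like genes, 1 of 35 splits of the 8 sums gave as many genes as the real 270, the highest other being 2, which says nothing on chance, since the classes were made from the expression of these cells. It is also the split of libraries 1 and 3 from 2 and 4. For plates all 35 splits gave at least the real 0, and the highest other was 525, from parting libraries 1 and 3 from 2 and 4, which points to that structure of the samples. Among the 8 splits that part the pairs of numbers the highest other was 0. For the luminal classes 4 splits within pairs are too few for a share under 0.05, with the real value 209, reached by 1 split, and the highest other 0.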
